A study of Arabidopsis thaliana with 10 samples.

How the data were processed

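RNA from dark-grown Arabidopsis hypocotyls was sequenced in 10 samples, which the labels place in 5 groups of 2, the second marked as a repeat. Wild-type Col-0 was on 1 µM PAC with 0 or 2 µM PPZ, each with 10 µM GA3 or mock for 12 hours, and bzr1-1D was on PAC and PPZ with mock. Per the series text, barcoded libraries were sequenced on an Illumina HiSeq2000 in pools of 6, and the labels name no pool for a sample. The submitters' processing notes name TopHat and DESeq. Their versions, the genome build, the annotation and the counting program are not given in the sources used here.

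The authors deposited 3 tables, one per comparison: GA3 against mock on PAC, GA3 against mock on PAC and PPZ, and bzr1-1D against wild type on PAC and PPZ. Per the file headers, each group's signal column is a mean of read counts divided by DESeq size factors by the authors, called normalized reads here. The fold column deposited by the authors is the ratio of the 2 group means, with the control as the denominator. The p-value columns, per the file headers, are the p and adjusted p of the authors' DESeq test. Each table holds 33518 genes and 5 rows that name no gene, which were left out of totals and tests. In those rows reads aligned to several places made up 8.61 to 10.7% of a group's total, reads outside genes 1.47 to 1.58% and ambiguous reads 1.34 to 1.47%. Gene symbols were taken by locus identifier from a RefSeq table of assembly TAIR10.1, in which 32709 of the 33518 identifiers matched. Since no build is named for the deposited tables, no coordinates are given.

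The main calls were those of the authors at a DESeq adjusted p under 0.05, with the direction from the deposited fold. The tables hold no column per library, so reads per library were recovered from the group means. Each low mean is a sum of whole multiples of 2 step sizes, 1 per library, which gave both size factors and then the whole reads of both libraries. In each group 99.6 to 100% of the genes with a mean above 0 came out as whole reads and were used (unresolved genes had means of at least 10046), and the recovery was tested on simulated data, where 1 gene in 22799 was wrong in 1 group and none in the other 4. The 2 libraries of a group are called deeper and shallower, since nothing ties them to the first sample or its repeat. The deposited size factors were 0.983 to 0.992 times those recomputed over all recovered libraries, so levels of different tables were compared on recovered reads scaled together. No 2 libraries of a group agreed within counting noise, with chi-square over degrees of freedom of 9.56, 3.30, 2.21, 2.58 and 4.68 in the 5 pairs.

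Log2 changes with standard errors came from limma-voom on the recovered reads (limma 3.58.1 in R 4.3.3), a second test chosen beforehand beside that of the authors. It kept genes with a mean of at least 10 normalized reads and resolved reads in all libraries of the fit, which leaves out some genes with high means. The genes kept were 19199 to 19659 per comparison, of which it called 6234, 6970 and 9241 at an adjusted p under 0.05. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold per comparison, limma-voom recovered 85% and 96% in the first comparison, 83% and 97% in the second and 87% and 99% in the third, with 14, 5 and 9 false calls. The simulated libraries were drawn independently, with the same dispersion for genes of similar mean. The real libraries may share other variation, so these rates need not hold for them. A limma-voom test of the difference between the GA3 effects with and without PPZ, and a comparison of PPZ with no PPZ on PAC in wild type, were fitted on the recovered reads. The latter has no deposited table and was added after the data were examined. Folds that rest on at most 30 reads on one side carry exact 95% intervals from the binomial split of the reads, for counting error alone.

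Overlaps of calls were tested with two-sided Fisher's exact tests among genes tested in both tables, beside the number that independent lists would share. The comparison that shares the wild-type PAC and PPZ libraries was also set against 100 simulated sets of unchanged groups, and its calls against 20 sets. For gene lists, the calls of 34 lists with 474 loci were tested with Fisher's exact test against the other tested genes, adjusted by Benjamini-Hochberg over 204 tests, and with camera at a preset and an estimated correlation. The Fisher tests were repeated with limma-voom calls, an alternative added after the data were examined. The lists were gibberellin biosynthesis, inactivation and perception, brassinosteroid biosynthesis, inactivation and signalling, Aux/IAA, SAUR, GH3 and auxin transport genes, ethylene, jasmonate, and cold and ABA genes. They also held HLH and bHLH growth regulators, the PIF family, shade and PIF targets, GASA peptides, expansins, xyloglucan endotransglucosylases, primary and secondary wall genes, aquaporins, cell cycle, clock, and photoreceptor and light signalling genes. Further lists were chlorophyll synthesis, light-harvesting, photosystem and Rubisco, flavonoid, touch and wounding, reference genes, and root, seed reserve and shoot meristem markers. These lists, the main tests, the alternatives and the rule for named genes were fixed before the data were examined, except where an alternative is stated to have been added.

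The named genes are, per comparison, the 8 with the largest increase and the 8 with the largest decrease among called genes with a higher mean of at least 50 normalized reads and a lower mean above 0. To these were added 21 genes fixed by name, up to 4 called members of each list that passed the Fisher test, and the 5 genes called in all 3 tables with the largest mean change. A few genes named beside their list, such as EXPA7 and GLR2.1, and the examples for PPZ, were chosen after their values were seen. The alternatives were stricter thresholds, adjusted p-values recomputed over other sets of genes, pseudocounts of 1 and 10, limma-voom with and without a filter and with trimmed mean scaling, and each library left out. Trimmed mean scaling moved the median log2 change by at most 0.04 in size and turned the direction of no list that passed. Further tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.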

Results

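Dark-grown Arabidopsis hypocotyls were compared in 5 groups of 2 sequencing libraries each, 10 libraries in all. Wild-type Col-0 seedlings grew for 4.5 days in the dark on 1 µM PAC (paclobutrazol, an inhibitor of gibberellin synthesis), with or without 2 µM PPZ (propiconazole, an inhibitor of brassinosteroid synthesis). They then received 10 µM GA3, an active gibberellin, or a mock solution, and RNA was taken 12 hours later. The fifth group was the dominant mutant bzr1-1D on PAC and PPZ with mock, in which the brassinosteroid-regulated transcription factor BZR1 is stabilized by a point mutation. Whole reads recovered from the deposited group means numbered 8035868 and 16414525 in the wild-type PAC libraries, 10765915 and 16198234 with GA3 on PAC, and 14748359 and 15423193 on PAC and PPZ. They numbered 11931685 and 15498303 with GA3 on PAC and PPZ, and 12181622 and 12721487 in bzr1-1D. These sums leave out genes with unresolved reads, which have high means, and so do not rank the libraries by depth. Such genes numbered 103 in bzr1-1D, 52 with GA3 on PAC and PPZ, 19 on PAC and PPZ, and 4 in each group without PPZ. Among genes with a mean of at least 1000 reads, the log2 difference between the libraries of a pair had an SD of 0.24 in the wild-type PAC pair and 0.09 to 0.16 in the other 4 pairs. The labels do not say that the libraries of a group came from separate cultures. Each p-value of a single gene therefore measures the spread between these libraries, which may be technical. The p-values of Fisher's exact test hold no such spread. They treat genes as independent draws, which the genes of a list are not.

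The question of the first comparison was which transcripts respond to GA3 when gibberellin synthesis is blocked. In wild type on PAC, GA3 raised many auxin-induced genes, expansins and aquaporins and lowered many flavonoid, photosystem and chlorophyll synthesis genes. PRE1 (AT5G39860), a small HLH protein that promotes cell elongation, was 42.0-fold higher in the authors' deposited table, where it reached 168 normalized reads (DESeq adjusted p = 2.54e-33). EXPA2 (AT5G05290), an expansin, was 16.5-fold higher and the auxin-inducible IAA19 (AT3G15540) was 5.40-fold higher in the authors' deposited table (DESeq adjusted p = 3.75e-37 and 6.88e-11). GA20OX3 (AT5G07200), which makes gibberellin precursors, was 22.3-fold lower, and PAP1 (AT1G56650), a MYB activator of anthocyanin synthesis, was 24.7-fold lower in the authors' deposited table (DESeq adjusted p = 7.48e-25 and 1.42e-46). On their few recovered reads on one side, 6 for PRE1, 24 for EXPA2, 23 for GA20OX3 and 15 for PAP1, the exact 95% intervals for counting error alone were 21.6 to 131, 11.02 to 26.2, 13.7 to 33.2 and 15.1 to 45.5-fold.

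By number, the authors' deposited table called 6536 of 24020 tested genes (27.2%), of which 3107 were higher and 3429 lower with GA3. Of these, 601 were at least 2-fold higher and 923 at least 2-fold lower in the authors' deposited table. The genes with the largest increases also included ACS5 (AT5G65800) and ACS11 (AT4G08040), which encode the ethylene precursor enzyme ACC synthase, WSD1 (AT5G37300), a wax ester synthase, and PME61 (AT3G59010), annotated as a pectin methylesterase. Their log2 changes in limma-voom on the recovered reads were 4.21 ± 0.34 (SE, 2 libraries per group), 3.71 ± 0.53, 4.05 ± 0.29 and 3.47 ± 0.28. AT3G59370 and AT5G46960 rose by 4.32 ± 0.32 and 3.47 ± 0.48.

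Gibberellin inactivation genes were higher, and single synthesis and receptor genes were lower. Among 6 measured gibberellin 2-oxidases, which inactivate the hormone, 4 were higher and none was lower (adjusted p = 0.0156 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). GA2OX2 (AT1G30040) rose by 3.04 ± 0.29 and GA2OX6 (AT1G02400) by 1.86 ± 0.15 on the log2 scale. Among 12 synthesis genes 5 were lower and 1 higher, which did not pass the list test (adjusted p = 0.0725 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). At the preset correlation the list passed as lower (camera adjusted p = 0.00329). GA3OX1 (AT1G15550), the final step of synthesis, changed by -1.80 ± 0.12, while GA20OX1 (AT4G25420) was not called in the authors' deposited table (DESeq adjusted p = 0.508) at 1.21-fold of its control. Of 11 perception and DELLA genes 4 were higher and 4 lower. The DELLA repressor RGA (AT2G01570) rose by 0.94 ± 0.11, and the receptors GID1A (AT3G05120) and GID1B (AT3G63010) changed by -0.65 ± 0.10 and -0.88 ± 0.13.

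Aux/IAA, SAUR, GH3 and brassinosteroid signalling genes were called higher more often than other genes. Of 27 Aux/IAA genes 13 were higher and 2 lower (adjusted p = 7.7e-05 by Fisher's exact test, and camera adjusted p = 0.652 with an estimated correlation). IAA29 (AT4G32280) rose by 1.31 ± 0.14 and IAA14 (AT4G14550) by 0.99 ± 0.15, whereas IAA27 (AT4G29080) changed by -1.28 ± 0.13. Of 20 SAUR genes, small auxin-induced transcripts tied to elongation, 12 were higher and none lower (adjusted p = 1.01e-05 by Fisher's exact test, and camera adjusted p = 0.616 with an estimated correlation), among them SAUR50 (AT4G34760) by 1.31 ± 0.19. Of 7 GH3 genes, which conjugate auxin to amino acids, 6 were higher (adjusted p = 0.000219 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with GH3.6 (AT5G54510) at 1.11 ± 0.12. Of 12 brassinosteroid signalling genes 6 were higher and none lower (adjusted p = 0.0109 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). The BZR1 homologues BEH4 (AT1G78700), BEH1 (AT3G50750) and BES1 (AT1G19350) rose by 1.16 ± 0.12, 1.19 ± 0.14 and 0.71 ± 0.11. Of 10 brassinosteroid synthesis genes 5 were higher and 1 lower (adjusted p = 0.0227 by Fisher's exact test, and camera adjusted p = 0.771 with an estimated correlation), but 4 of 10 were higher in limma-voom, where the list did not pass (adjusted p = 0.17 by Fisher's exact test). DWF4 (AT3G50660), a rate-limiting enzyme of that pathway, rose by 0.67 ± 0.15, a call that ended without the deeper library of the wild-type PAC and GA3 pair (log2 change 0.58, limma-voom adjusted p = 0.0618, over all refits 9.19e-10 to 0.0618).

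Many expansins, aquaporins and lignin genes were higher, whereas none of 8 primary wall cellulose genes was called and 8 of 29 xyloglucan endotransglucosylases were higher and 5 lower, which did not pass the Fisher test. Of 21 expansins 11 were higher and none lower (adjusted p = 0.000132 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with EXPA8 (AT2G40610) at 1.93 ± 0.12 and EXPB1 (AT2G20750) at 2.16 ± 0.17. Of 17 aquaporins, which carry water into growing cells, 12 were higher (adjusted p = 1.11e-06 by Fisher's exact test, and camera adjusted p = 0.562 with an estimated correlation), including PIP2;7 (AT4G35100) by 1.42 ± 0.15. Of 15 secondary wall and lignin genes 12 were higher and 2 lower (adjusted p = 1.14e-07 by Fisher's exact test, and camera adjusted p = 0.656 with an estimated correlation), for example 4CL1 (AT1G51680) by 0.89 ± 0.10 and CESA8 (AT4G18780) by 0.81 ± 0.15. Of 16 cell cycle genes 7 were higher and 1 lower (adjusted p = 0.0118 by Fisher's exact test, and camera adjusted p = 0.656 with an estimated correlation), among them CYCD1;1 (AT1G70210) and CDKB2;1 (AT1G76540) by 0.96 ± 0.13 and 0.94 ± 0.14. Of 10 shade and PIF target genes 7 were higher (adjusted p = 0.000355 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), such as ATHB2 (AT4G16780) by 0.78 ± 0.11. PIF4 (AT2G43010), a bHLH factor that promotes hypocotyl elongation, rose by 1.01 ± 0.12.

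Photosynthesis and pigment genes were lower. Of 27 nuclear photosystem and Rubisco genes 23 were lower and none higher (adjusted p = 2.24e-14 by Fisher's exact test, and camera adjusted p = 0.656 with an estimated correlation), with RBCS1B (AT5G38430) at -2.01 ± 0.19 and PSBS (AT1G44575) at -1.04 ± 0.15. Of 21 chlorophyll synthesis genes 19 were lower (adjusted p = 5.32e-13 by Fisher's exact test, and camera adjusted p = 0.581 with an estimated correlation), among them PORA (AT5G54190) at -1.40 ± 0.19 and CHLG (AT3G51820) at -1.02 ± 0.12. Of 21 light-harvesting genes 10 were lower and 1 higher (adjusted p = 0.00162 by Fisher's exact test, and camera adjusted p = 0.851 with an estimated correlation), but in limma-voom 6 of 20 were lower, which did not pass (adjusted p = 0.294 by Fisher's exact test). Photosystem and Rubisco genes called lower in limma-voom were 13 of 26 (adjusted p = 0.000795 by Fisher's exact test). Of 15 flavonoid genes 11 were lower (adjusted p = 4.64e-06 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). The late anthocyanin genes DFR (AT5G42800) and LDOX (AT4G22880) fell from 257 and 276 reads over both control libraries to 3 reads each. Those counts give falls of 93.0-fold (exact 95% interval 31.5 to 454) and 99.9-fold (33.8 to 487) for counting error alone. GSTF12 (AT5G17220) and UGT79B1 (AT5G54060), also of the anthocyanin pathway, kept 2 and 1 reads. The acyltransferase AT5MAT (AT3G29590) and the seed caleosin ATS1 (AT4G26740) changed by -5.48 ± 0.75 and -4.95 ± 0.81. In the same comparison 10 of 13 seed reserve markers were lower and 1 higher (adjusted p = 7.05e-06 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), for example the storage proteins CRU2 (AT1G03880) and SESA3 (AT4G27160) by -3.31 ± 0.24 and -2.96 ± 0.24.

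The remaining lists did not pass the Fisher test in this comparison. They held 5 of 17 HLH and bHLH growth regulators, 5 of 18 ethylene genes, 4 of 15 cold and ABA genes, 3 of 12 clock genes and 3 of 7 PIF genes called higher. Among the 11 reference genes 4 were called higher and 2 lower, and 1 of 11 root markers was called higher. HY5 (AT5G11260), a light-signalling bZIP factor, and PRE6 (AT1G26945) were not called. Adjusted over the list alone, the counts rose by 1 gene in BR signalling (7 higher), SAUR (13), shade targets (8), cell cycle (2 lower) and expansins (1 lower), and the other lists that passed the test kept theirs, except seed reserves with 2 higher. No list call in the 3 comparisons held in camera with an estimated correlation, where 52 of 204 tests passed by Fisher's exact test. At the preset correlation 52 camera tests passed, not all of them for the same lists. The estimated correlation rests on 2 libraries per group, and the lowest adjusted p it gave in camera was 0.54. It may therefore lack the power to pass any list. Without the deeper library of the wild-type PAC and GA3 pair, limma-voom called 2613 genes, against 6234 with all 4 libraries and 3718 without the shallower one. Reads that aligned to several places, 8.61 to 10.7% of each group's total, were set apart in the authors' deposited table, so values of near-identical family members (LHCB1, RBCS, SAUR, PIP and SESA genes) are uncertain.

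The question of the second comparison was which of these responses are seen when brassinosteroid synthesis is also blocked. On PAC and PPZ, GA3 raised many expansins and lowered many gibberellin synthesis, anthocyanin and photosynthesis genes. EXPA8 was 14.4-fold higher in the authors' deposited table, from 20.8 to 299 normalized reads (DESeq adjusted p = 1.82e-32). XTH16 (AT3G23730), a xyloglucan endotransglucosylase that remodels the wall, was 5.30-fold higher and GASA6 (AT1G74670), a gibberellin-regulated peptide, was 6.29-fold higher in the authors' deposited table (DESeq adjusted p = 1.44e-98 and 2.34e-109). GA20OX3 and GA20OX2 (AT5G51810) were 31.6-fold and 11.1-fold lower in the authors' deposited table (DESeq adjusted p = 5.27e-27 and 1.47e-09). GA20OX3 kept 14 reads over both libraries with GA3, which gives an exact 95% interval of 17.5 to 54.8-fold.

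The authors' deposited table called 3269 of 24513 tested genes (13.3%), 1463 higher and 1806 lower, of which 261 and 335 changed at least 2-fold. EXPA2 and the alternative NAD(P)H dehydrogenase NDB3 (AT4G21490) rose by 3.24 ± 0.21 and 3.54 ± 0.31 on the log2 scale in limma-voom (SE, 2 libraries per group). AT5G46960, AT1G06360 and AT1G29090 rose by 3.81 ± 0.34, 2.80 ± 0.12 and 2.74 ± 0.13. DFR, LDOX and PAP1 changed by -5.19 ± 0.36, -4.59 ± 0.28 and -4.03 ± 0.23. PRE1 was called higher in the authors' deposited table (DESeq adjusted p = 0.000449), but it stood at 0.426 and 9.45 normalized reads, too few for a fold. For PRE1 the test of the difference from the GA3 effect without PPZ did not pass (limma-voom adjusted p = 0.285).

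Gibberellin synthesis genes were called lower more often than other genes here, with 6 of 12 lower and 1 higher (adjusted p = 0.000676 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). The difference from the GA3 effect without PPZ did not pass for this list at the preset correlation (camera adjusted p = 0.609). GA20OX1 and GA3OX1 changed by -2.38 ± 0.38 and -1.86 ± 0.08. Of 7 inactivation genes 3 were higher (adjusted p = 0.0263 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), including GA2OX6 by 1.66 ± 0.14. Of 11 perception and DELLA genes 4 were higher (adjusted p = 0.0142) and 4 lower (adjusted p = 0.0265, both by Fisher's exact test, and camera adjusted p = 0.874 with an estimated correlation). Neither direction passed with limma-voom calls (adjusted p = 0.264 and 0.276 by Fisher's exact test). The members that rose included the DELLA genes GAI (AT1G14920) and RGA, by 1.09 ± 0.06 and 0.95 ± 0.05. The receptor gene GID1B changed by -1.43 ± 0.11, and SCL3 (AT1G50420), a GRAS protein gene that promotes gibberellin responses, fell from 1310 to 327 normalized reads in the authors' deposited table (DESeq adjusted p = 7.36e-61).

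Expansins, HLH regulators and Aux/IAA genes were called higher more often than other genes in this background, of which the HLH list had not passed the Fisher test without PPZ. At the preset correlation the HLH list passed without PPZ too (camera adjusted p = 0.0406). The difference between its GA3 effects with and without PPZ did not pass at that correlation (camera adjusted p = 0.388). Of 21 expansins 10 were higher and 1 lower (adjusted p = 1.56e-06 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with EXPA3 (AT2G37640) at 2.01 ± 0.06 and EXPA1 (AT1G69530) at 1.07 ± 0.07. Of 29 xyloglucan endotransglucosylases 9 were higher and 3 lower (adjusted p = 0.00023 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). XTH23 (AT4G25810) rose by 1.26 ± 0.10 and XTH31 (AT3G44990) changed by -0.91 ± 0.05. Of 18 HLH and bHLH growth regulators 8 were higher and 1 lower (adjusted p = 3.57e-05 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). PRE5 (AT3G28857), HBI1 (AT2G18300) and BEE2 (AT4G36540), which promote elongation, rose by 2.09 ± 0.24, 0.85 ± 0.06 and 0.73 ± 0.06, and AIF3 (AT3G17100), which opposes it, rose by 0.79 ± 0.05. Of 27 Aux/IAA genes 11 were higher and 2 lower (adjusted p = 2.4e-06 by Fisher's exact test, and camera adjusted p = 0.627 with an estimated correlation), among them IAA19 by 2.02 ± 0.16 and IAA7 (AT3G23050) by 1.18 ± 0.06.

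Smaller groups followed. Of 16 cell cycle genes 8 were higher (adjusted p = 1.28e-05 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with CYCD1;1 and KNOLLE (AT1G08560), the cell plate syntaxin, at 1.27 ± 0.07 and 1.01 ± 0.10. Of 10 shade and PIF targets 7 were higher (adjusted p = 3.47e-06 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). Of 12 brassinosteroid signalling genes 5 were higher (adjusted p = 0.00231 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), of 17 aquaporins 6 (adjusted p = 0.00182 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation) and of 6 GH3 genes 3 (adjusted p = 0.0168 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). In limma-voom 10 of 16 aquaporins were higher (adjusted p = 0.000692 by Fisher's exact test). The tonoplast aquaporin TIP2;1 (AT3G16240) rose by 1.61 ± 0.06. Of 20 SAUR genes 3 were higher and 1 lower, and of 15 secondary wall genes 1 was higher and 1 lower, neither past the Fisher test.

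Photosynthesis, pigment and seed reserve genes were lower here too. Of 27 photosystem and Rubisco genes 16 were lower (adjusted p = 1.23e-10 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with PSBO2 (AT3G50820) at -0.82 ± 0.05. Of 21 chlorophyll synthesis genes 14 were lower and 1 higher (adjusted p = 2.4e-10 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), and of 21 light-harvesting genes 12 were lower (adjusted p = 7.19e-08 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with CHLH (AT5G13630) and LHCB1.1 (AT1G29920) at -0.61 ± 0.03 and -1.40 ± 0.06. In limma-voom 23 of 24 photosystem and Rubisco genes and 18 of 19 light-harvesting genes were lower (adjusted p = 2.7e-14 and 2.94e-11 by Fisher's exact test), so whether more of them fell without or with PPZ depends on the test. Of 14 flavonoid genes 10 were lower (adjusted p = 7.14e-08 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), such as FLS1 (AT5G08640) by -1.79 ± 0.07. Of 13 seed reserve markers 10 were lower and 1 higher (adjusted p = 2.43e-08 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with CRU2 and SESA3 at -3.04 ± 0.26 and -3.45 ± 0.20, and 1 of 12 root markers was lower. Among lists that did not pass, 4 of 17 ethylene genes, 3 of 10 touch and wounding genes, 2 of 11 reference genes and 2 of 12 clock genes were higher, and 3 of 15 cold and ABA genes were lower. Adjusted over the list alone, 23 photosystem genes, 18 chlorophyll genes and 13 light-harvesting genes were lower, and 9 cell cycle genes (1 lower), 8 shade targets, 7 aquaporins, 6 BR signalling genes and 10 xyloglucan endotransglucosylases were higher. The same adjustment gave 12 Aux/IAA genes higher and 3 lower, 11 flavonoid and 11 seed reserve genes lower, and 2 HLH genes and 2 expansins lower, and left the gibberellin and GH3 lists as above. Limma-voom on the recovered reads called 6970 genes, which included 3225 of the 3269 in the same direction and none in the opposite one. Without PPZ it called 6234, and with all groups in 1 fit it called 7920 without and 4543 with PPZ. Which of the GA3 comparisons had more calls therefore depends on the test.

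Set side by side, the GA3 responses without and with PPZ ran the same way and were smaller with PPZ. Of genes called higher with PPZ, 1162 (79.4%) were also called higher without it, where independent lists would share 194. Of genes called lower with PPZ, 1549 (85.8%) were also lower without it, against 264 (Fisher's exact test, two-sided, odds ratios 39.8 and 63.4). Opposite calls were 14 in one pairing and 0 in the other. Shared calls included EXPA2 and RGA, which rose, and GA3OX1, PAP1, DFR and CRU2, which fell, in both. Across 18972 genes with a mean of at least 10 normalized reads, the log2 fold changes had a Spearman rho of 0.723, where genes are not independent replicates.

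The size of the response was compared gene by gene. Among 6515 genes called without PPZ, the median ratio of log2 fold changes with over without PPZ was 0.539, and 94.7% kept their sign. Among 3256 genes called with PPZ, a choice that favours the other table, it was 0.826. In the 2717 genes called in both and with a defined ratio, it was 0.754. A limma-voom test of the difference itself found 678 of 19494 genes past an adjusted p of 0.05, 362 with a more positive and 316 with a more negative effect with PPZ. Among 6977 genes called in either GA3 comparison, 666 differed, 646 against and 20 along the direction of the effect without PPZ. That effect is itself part of the tested difference, and 6445 of these genes were called in it. Noise in it favours the first side, so the split alone does not show smaller responses. Among genes called without PPZ and not with it the split was 343 and 0, and among those called with PPZ 303 and 20. The 646 hold smaller responses but also turned ones, such as that of GA20OX1, which was called lower only with PPZ. Of 33 that differed among genes called with PPZ and not without it, 24 were among the 646. AT3G59370 differed by -3.98 ± 0.38 (limma-voom adjusted p = 0.00112), and XTH16 by 1.15 ± 0.15 (limma-voom adjusted p = 0.00389), with a larger rise on PPZ. GA20OX1 differed by -2.70 ± 0.52 (limma-voom adjusted p = 0.0197), a call that held in 3 of 8 refits without 1 library each (highest limma-voom adjusted p = 0.0898), while AT3G59370 and XTH16 passed in all 8. Of the secondary wall genes, 12 of 15 called higher without PPZ and 1 with it, 3 passed the test of the difference, all lower (adjusted p = 0.0174 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). Of 19 SAUR genes none passed it (limma-voom, adjusted over all genes). The count of differing genes was 2742 without the shallower wild-type PAC library and lay between 53 and 291 without each library of the other 3 wild-type groups in turn. Trimmed mean scaling gave 314 genes with a more positive and 341 with a more negative effect, so the larger side depends on the scaling, and it was the negative one without each library of these 3 groups too.

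**Figure D1:**
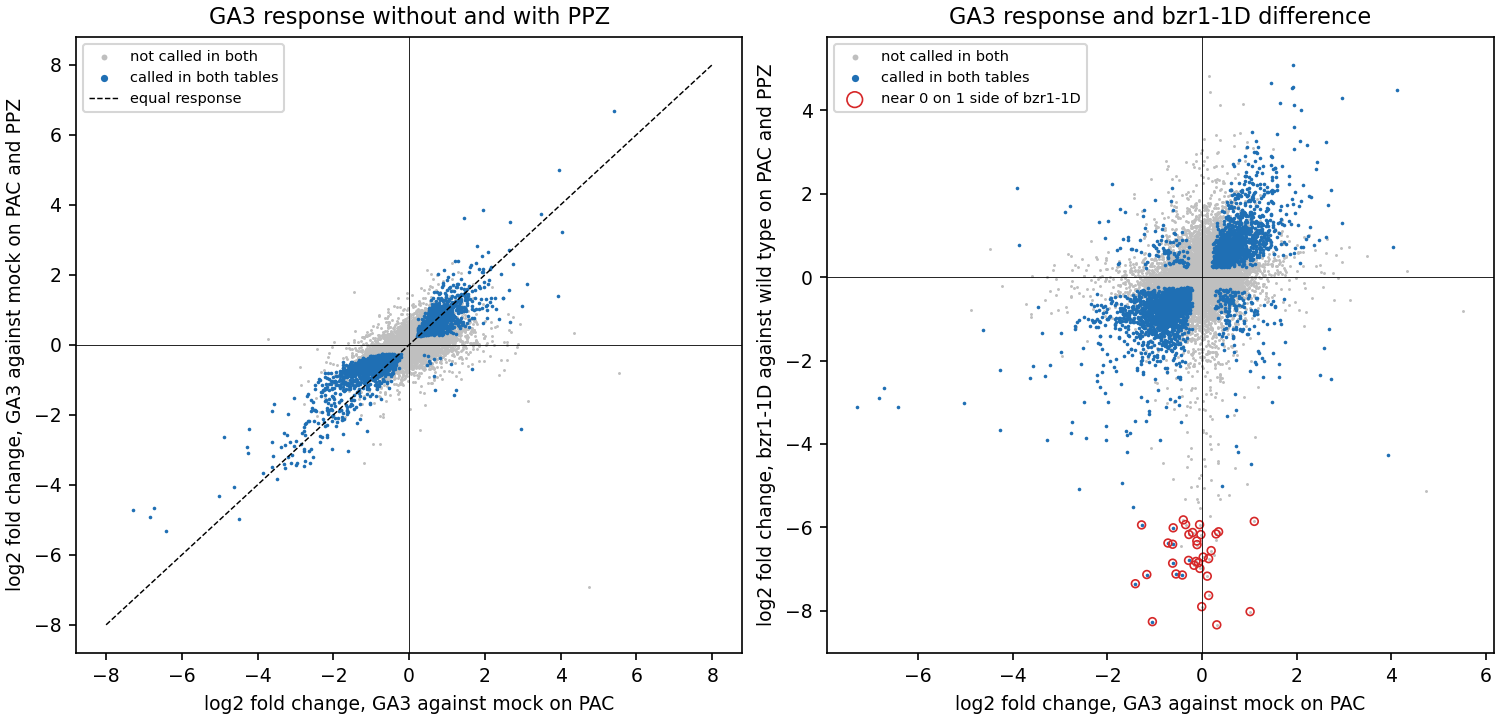
Log2 fold changes of genes with a mean of at least 10 normalized reads in both tables: GA3 on PAC (x axis) against GA3 on PAC and PPZ (left, y axis) and against bzr1-1D over wild type (right, y axis), with genes called in both tables in blue and genes near 0 reads on one side in red circles (those near 0 in wild type fall under the minimum and are not drawn). The left cloud follows the diagonal with a Spearman rho of 0.723 and lies nearer to 0 on its y axis, and the right one has a rho of 0.493.

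The question of the third comparison was which transcripts active BZR1 changes when brassinosteroid synthesis is blocked. In bzr1-1D on PAC and PPZ, auxin-induced SAUR genes were higher, and photosynthesis, flavonoid and several brassinosteroid synthesis genes were lower, than in wild type. BR6OX2 (AT3G30180), the last step of brassinolide synthesis, was 11.1-fold lower in the authors' deposited table, from 5602 to 504 normalized reads (DESeq adjusted p = 5.91e-214). EXPA8 was 12.1-fold higher and SAUR24 (AT5G18080) was 8.67-fold higher in the authors' deposited table (DESeq adjusted p = 1.38e-29 and 1.94e-20). SAUR24 had 25 reads over both wild-type libraries, which gives an exact 95% interval of 5.68 to 13.6-fold. LHCB1.4 (AT2G34430), a light-harvesting protein, was 10.1-fold lower in the authors' deposited table (DESeq adjusted p = 2.39e-111). BZR1 (AT1G75080) itself changed by 0.59 ± 0.09 on the log2 scale in limma-voom (SE, 2 libraries per group), which does not check the labels, since the mutation alters the protein.

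The authors' deposited table called 7276 of 24621 tested genes (29.6%), 3579 higher and 3697 lower, of which 1081 and 1204 changed at least 2-fold. Brassinosteroid synthesis genes were 5 of 10 lower and 2 higher (adjusted p = 0.0396 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), a list that did not pass with limma-voom calls (adjusted p = 0.115 by Fisher's exact test). DWF4, CYP90D1 (AT3G13730), BR6OX1 (AT5G38970) and CPD (AT5G05690) changed by -1.45 ± 0.08, -1.93 ± 0.14, -1.62 ± 0.17 and -0.52 ± 0.07. Both brassinosteroid inactivation genes were higher, a list too small to pass the Fisher test. Of 12 signalling genes 7 were higher and 1 lower (adjusted p = 0.00295 by Fisher's exact test, and camera adjusted p = 0.693 with an estimated correlation), among them the receptor BRI1 (AT4G39400) by 0.37 ± 0.08 and the kinase BIN2 (AT4G18710), which restrains BZR1, by 0.47 ± 0.07.

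SAUR and Aux/IAA genes and HLH growth regulators were called higher more often than other genes. Of 20 SAUR genes 18 were higher and none lower (adjusted p = 3.89e-12 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). SAUR16 (AT4G38860), SAUR66 (AT1G29500) and SAUR21 (AT5G18030) rose by 2.98 ± 0.26, 2.65 ± 0.23 and 2.65 ± 0.23. Of 27 Aux/IAA genes 12 were higher and 2 lower (adjusted p = 0.00118 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with IAA19 at 2.75 ± 0.21 and IAA17 (AT1G04250) at 1.48 ± 0.09. Of 6 auxin transport genes 4 were higher and 1 lower (adjusted p = 0.0227 by Fisher's exact test, and camera adjusted p = 0.771 with an estimated correlation), with the influx carrier AUX1 (AT2G38120) at 0.48 ± 0.08. Of 17 HLH and bHLH growth regulators 9 were higher (adjusted p = 0.00142 by Fisher's exact test, and camera adjusted p = 0.593 with an estimated correlation). PAR2 (AT3G58850), which restrains shade growth, rose by 1.93 ± 0.16, and PRE5 and PRE6 rose by 1.71 ± 0.25 and 1.65 ± 0.10. Of 7 PIF genes 4 were higher and 1 lower (adjusted p = 0.0424 by Fisher's exact test, and camera adjusted p = 0.552 with an estimated correlation), with PIF4 at 1.11 ± 0.11. With limma-voom calls the auxin transport and PIF lists did not pass (adjusted p = 0.111 and 0.334 by Fisher's exact test).

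Xyloglucan endotransglucosylases and expansins moved in both directions, while the aquaporin, primary wall and secondary wall genes that were called mostly rose. Of 29 xyloglucan endotransglucosylases 12 were higher and 8 lower (adjusted p = 0.00229 by Fisher's exact test, and camera adjusted p = 0.593 with an estimated correlation), for example XTH5 (AT5G13870) by 2.41 ± 0.11 and XTH32 (AT2G36870) by -1.31 ± 0.08. Of 21 expansins 8 were higher and 7 lower (adjusted p = 0.0279 by Fisher's exact test, and camera adjusted p = 0.91 with an estimated correlation), and their median log2 fold change was 0.04, or -0.03 among members with a mean of at least 10 normalized reads. Members that fell included the root hair expansins EXPA7 (AT1G12560) and EXPA18 (AT1G62980), and of 12 root markers 7 were lower and none higher (adjusted p = 0.00353 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). COW1 (AT4G34580), a root hair gene, and PRP3 (AT3G62680) changed by -3.07 ± 0.27 and -1.98 ± 0.23. Of 17 aquaporins 11 were higher and 1 lower (adjusted p = 2.96e-05 by Fisher's exact test, and camera adjusted p = 0.593 with an estimated correlation), including PIP2;2 (AT2G37170) by 1.24 ± 0.11. Of 8 primary wall cellulose genes 6 were higher (adjusted p = 0.00129 by Fisher's exact test, and camera adjusted p = 0.656 with an estimated correlation), with the cellulose synthase CESA6 (AT5G64740) at 0.54 ± 0.08. Of 15 secondary wall and lignin genes 7 were higher and 1 lower (adjusted p = 0.0142 by Fisher's exact test, and camera adjusted p = 0.771 with an estimated correlation). With limma-voom calls the expansin, primary wall and secondary wall lists did not pass (adjusted p = 0.266, 0.232 and 0.0537 by Fisher's exact test). Only 5 of the 8 primary wall genes were fitted, 3 of them higher. Genes with unresolved reads are not fitted, so this result does not cover the same primary wall genes. Of 15 cold and ABA genes 10 were higher (adjusted p = 5.26e-05 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with the dehydrins COR47 (AT1G20440) and ERD10 (AT1G20450) at 2.00 ± 0.10 and 1.72 ± 0.09.

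Photosynthesis genes were lower almost throughout. All 27 photosystem and Rubisco genes were lower (adjusted p = 1.1e-20 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), for example PSAO (AT1G08380) by -1.76 ± 0.08. All 21 chlorophyll synthesis genes were lower (adjusted p = 4.95e-16 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with GUN4 (AT3G59400) and HEMA1 (AT1G58290) at -1.94 ± 0.10 and -1.32 ± 0.09. Of 21 light-harvesting genes 20 were lower and 1 higher (adjusted p = 2.99e-14 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation). Of 15 flavonoid genes 11 were lower (adjusted p = 7.05e-06 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with CHS (AT5G13930), which opens the pathway, at -2.24 ± 0.08. HY5 changed by -0.84 ± 0.11. Gibberellin genes showed few calls, with 2 of 12 synthesis, 1 of 7 inactivation and 3 of 11 perception genes higher and none lower. GA3OX1 rose by 0.65 ± 0.08.

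In 53 called genes one group was near 0, with at most 2% of the other group's mean, and the other mean was at least 50 normalized reads. These 53 genes, 16 higher and 37 lower in bzr1-1D, held all 16 genes with the largest folds, and 45 had no symbol. The retroelement SADHU5-2 (AT5G27927) had 1 read in wild type and 402 in bzr1-1D (427-fold, exact 95% interval 76.2 to 16903), and PP2-A8 (AT5G45070), of the phloem protein 2 family, had 269 and 1 (253-fold lower, 45.1 to 10042). AT1G24370 rose from 5 reads to 1770 (376-fold, 161 to 1159), and AT5G56380 fell from 1823 to 12 (143-fold, 81.7 to 277), with intervals that cover counting error alone. The GA3 comparisons held 4 and 0 such genes.

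The other lists did not pass the Fisher test in bzr1-1D. Higher members were 4 of 12 GASA peptides, 2 of 6 GH3 genes, 4 of 10 shade targets, 3 of 16 cell cycle genes, 6 of 17 ethylene genes, 3 of 10 touch genes, 4 of 11 reference genes and 1 of 4 shoot meristem markers. Lower members were 4 of 13 photoreceptor and light signalling genes, 5 of 16 jasmonate genes, 4 of 12 clock genes and 4 of 13 seed reserve markers. Adjusted over the list alone, 8 BR signalling and 8 secondary wall genes were higher, 1 SAUR and 2 HLH genes were also lower, and the other lists that passed kept their counts. Limma-voom called 9241 genes here, which included 7042 of the 7276 in the same direction.

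**Figure D2:**
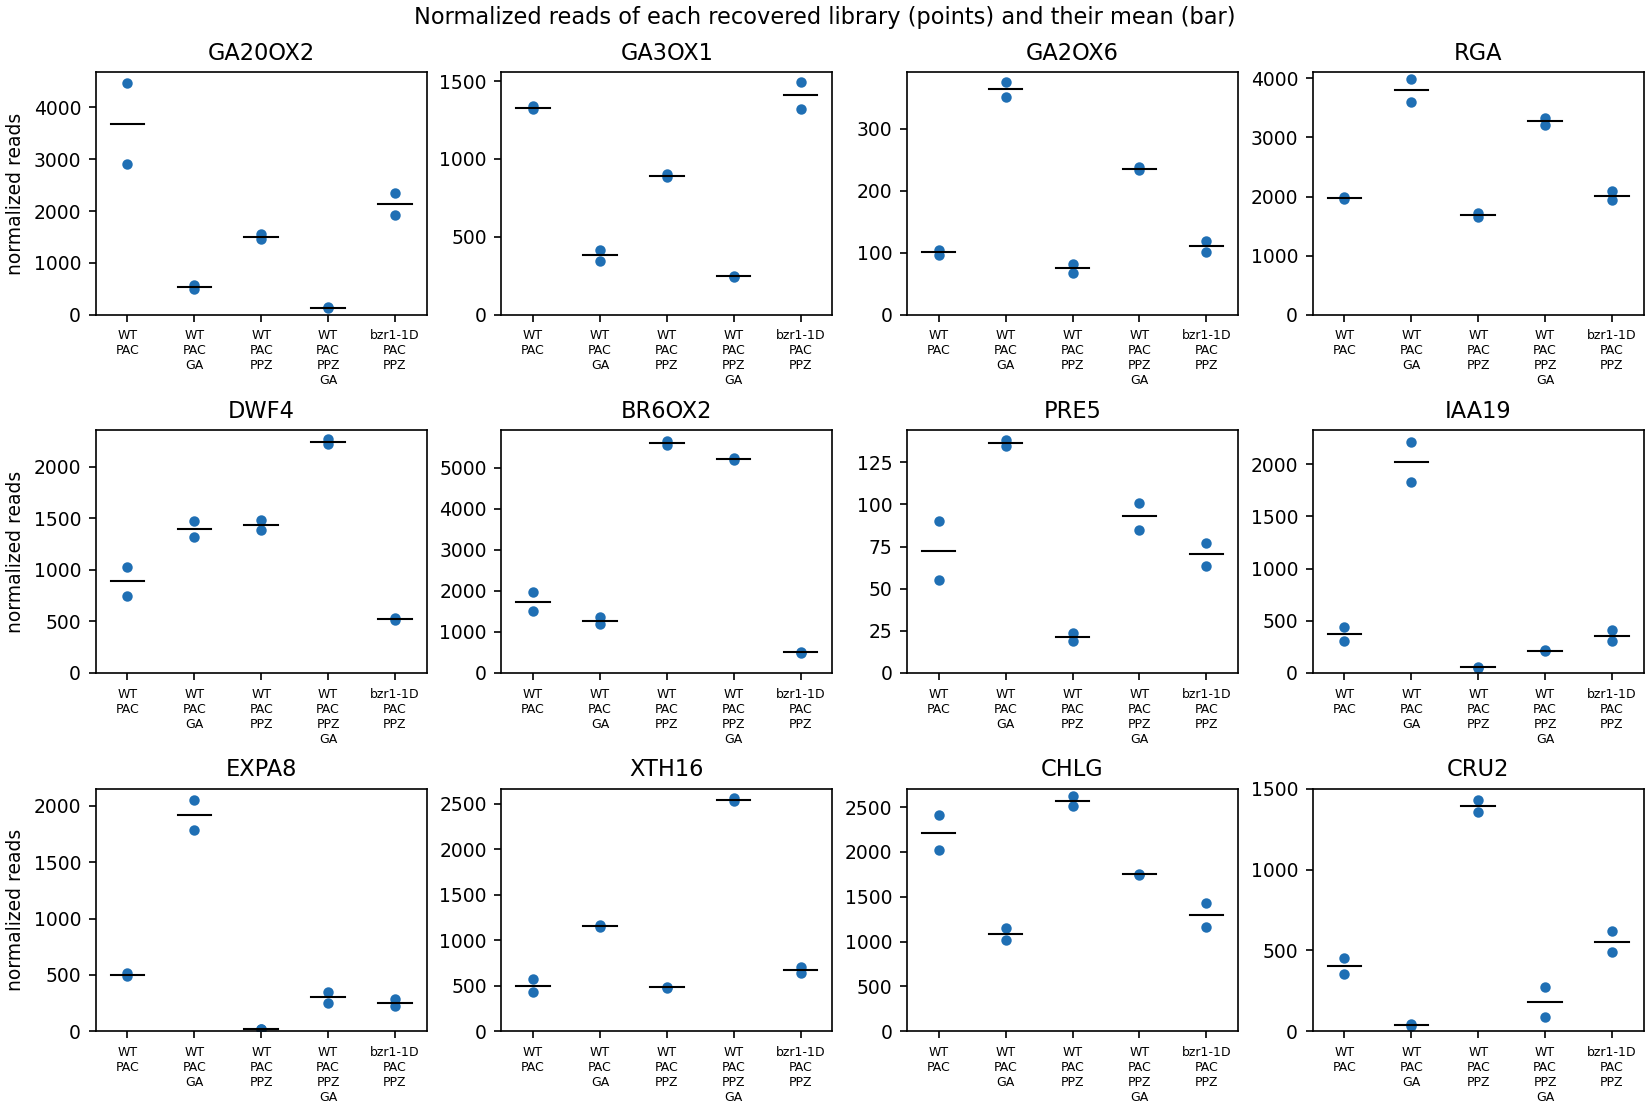
Normalized reads (linear y axis from 0) of 12 genes in the 5 groups, with 1 point per recovered library and a bar at the mean of the pair. EXPA8 is near 20.8 on PAC and PPZ and rises to 299 with GA3 and to 252 in bzr1-1D, and BR6OX2 falls from 5602 to 504 in bzr1-1D.

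**Figure D3:**
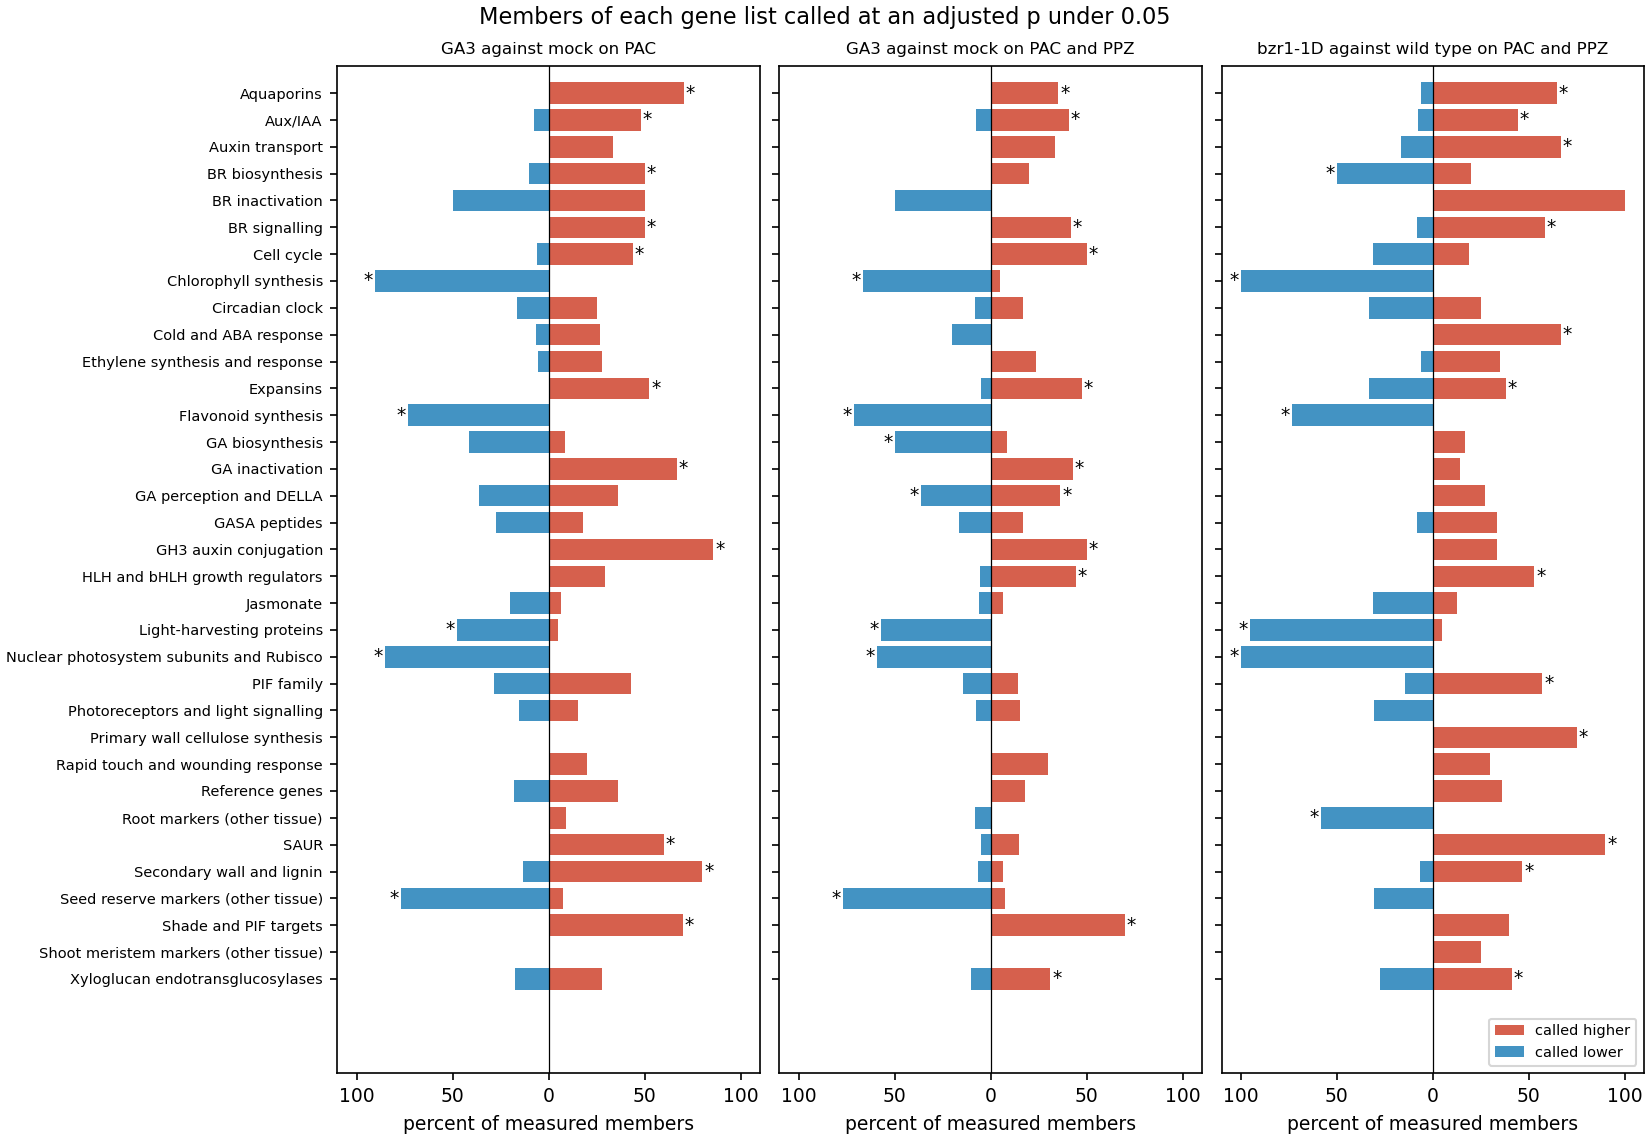
Percent of the measured members of each gene list called higher (red, to the right) and lower (blue, to the left) in the 3 comparisons, with a star where Fisher's exact test gave an adjusted p under 0.05 for enrichment. Photosystem genes reach 23 of 27 lower with GA3 on PAC, 16 of 27 with GA3 on PAC and PPZ, and 27 of 27 in bzr1-1D, while limma-voom called 13 of 26, 23 of 24 and 24 of 24 lower.

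The series title names a common module of brassinosteroid and gibberellin, and the last comparisons asked how far bzr1-1D and GA3 changed the same transcripts. EXPA8, IAA19 and PIF4 rose, and FLS1, PORA and RBCS1B fell, both with GA3 on PAC and in bzr1-1D. Of genes called with GA3 on PAC, 1533 were higher in both (471 for independent lists) and 1898 lower in both (540), by Fisher's exact test with odds ratios of 8.83 and 12.6. Opposite calls were fewer than for independent lists, with 188 higher with GA3 and lower in bzr1-1D (489) and 108 the reverse (520). These comparisons share no library, and their log2 fold changes had a Spearman rho of 0.493 across 18964 genes. GA3OX1 was among the opposite ones, lower with GA3 and higher in bzr1-1D.

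With GA3 on PAC and PPZ, 715 genes were higher in both (216 for independent lists) and 1156 lower in both (277), while 112 and 99 were opposite (225 and 267). These comparisons share the wild-type PAC and PPZ libraries, which adds to such overlaps without any effect. Unchanged groups simulated against these controls gave a covariance of log2 fold changes of 0.0176, against 0.114 observed, while their correlation was 0.493 against 0.314 observed. With a separate control library for each comparison the observed r was 0.265 and 0.256. Genes of the same sign made up 68.0% of those observed and 66.5% of those simulated (67.3% at the highest). The simulated groups shared no call in 20 draws, but they held at most 1 call with GA3 and 0 in bzr1-1D. This could not gauge the number of shared calls, and part of the excess may still come from the shared controls. In all 3 comparisons 1827 genes were called, of which 632 were higher and 1058 lower in each. The anthocyanin genes UGT79B1, DFR, GSTF12, AT5MAT and LDOX had the largest mean changes among these, all lower. In 128 genes both GA3 comparisons ran one way and bzr1-1D the other.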

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

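All tests of explanations in this part were chosen after the result was seen, except the test of the PPZ effect on the genes near 0 reads, and the test of the difference between GA3 effects was fixed beforehand.

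The GA3 effect differed with and without PPZ in 678 genes by a limma-voom test of the difference itself (3431 at an unadjusted p under 0.05). Among named genes the effect was smaller with PPZ in AT3G59370 (difference -3.98 on the log2 scale), the ACC synthase ACS5 (-3.23) and the wax ester synthase WSD1 (-5.39). WSD1 had 0 reads in both libraries with GA3 on PAC and PPZ, so the size of its fitted difference depends on the offset of the fit. The effect was also smaller in the auxin-conjugating GH3.2 (-1.41) and GH3.17 (-0.72), the expansin EXPB1 (-1.06), the wall enzyme gene XTH18 (-1.01), the aquaporins PIP2;7 (-0.85) and PIP1;4 (-0.55), and 4CL1 of lignin synthesis (-0.59). Among genes that GA3 lowered, the fall was smaller with PPZ in IAA27 (0.57), CHLI1 (0.58) and PSAH2 (0.54), and GA20OX1 fell only with PPZ (-2.70). On the log2 scale the rise was larger with PPZ in EXPA8 (1.85), XTH16 (1.15), AT1G06360 (0.99), EXPA3 (0.85) and GASA6 (0.56), and BEE2 rose only with PPZ (0.60). In normalized reads EXPA8 rose from 23.0 and 18.6 to 252 and 346 with PPZ. It rose by more reads without PPZ, from 486 and 515 to 2052 and 1784. Without each of the 8 libraries in turn, AT3G59370 and XTH16 passed the test in all 8 refits (highest limma-voom adjusted p = 0.0120 and 0.0442), and the other 18 genes lost it in at least 1.

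The smaller GA3 response with PPZ may reflect a need for brassinosteroid in part of the response, a biological explanation that the design offers and that was not tested apart from other effects of PPZ. A choice of genes on the values of 1 table would give a ratio above 1 among genes called with PPZ, and the ratio there was 0.826, and 0.744 to 0.879 without each library in turn. A single library of the wild-type PAC or PAC and GA3 pairs as the source would bring the ratio to 0.9 without it. Without the deeper PAC library it was 0.622 for genes called without PPZ, a choice that favours a low ratio, and 0.879 for genes called with PPZ, so a part played by this library cannot be told apart. Whether PPZ acts through brassinosteroid or otherwise also stays open.

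In bzr1-1D, 53 called genes were near 0 reads on one side, among them the glutamate receptor gene GLR2.1, which was lower. If these genes followed the action that BZR1 loses on PPZ, PPZ in wild type would move them against their bzr1-1D change by over 1 on the log2 scale, but the median was 0.16 (95% bootstrap interval 0 to 0.44) beside a median bzr1-1D change of 6.29. A block of chromosome 1 carried along with the mutation cannot hold the 32 genes (60.4%, exact 95% interval 46.0 to 73.5) on chromosomes 3, 4 and 5, and of the 21 genes on chromosome 1, 4 (19.0%, 5.45 to 41.9) lay in the 25% of its loci nearest BZR1. A line that differs from wild type at many places may account for the 13.25-fold larger number than in the GA3 comparisons, and 17 of the genes lay within 10 loci of another, against 1.79 on average and at most 10 in 1000 random draws. It cannot be told apart from an effect of the mutation, since bzr1-1D was the one mutant line. No such gene lay on chromosome 2, which held 14.9% of all genes at that level, so the genes were unevenly spread over the genome.

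Root marker transcripts were lower in bzr1-1D, with a median log2 change of -2.01 over 10 fitted markers. A smaller share of root tissue in those libraries would lower them alike if all root zones changed alike. Their log2 changes had an SD of 1.01, 3.33 times their median standard error of 0.304, and 0.794 without SCR, which the shoot endodermis also expresses. The markers need not stem from a single root zone, so this spread cannot decide whether a different share of root tissue is the explanation. The same markers were higher with PPZ in wild type, 9 of 10 of them, but both comparisons use the wild-type PAC and PPZ libraries, so more root tissue there could give both. With GA3 against the same libraries 1 of 12 was lower. An effect of BZR1 on root hair genes was not tested.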

How the results depend on the processing

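The alternatives for the counts of called genes were chosen before the result was seen, except the fit of all groups together, the limma-voom overlaps and every refit of the PPZ comparison and of the difference between GA3 effects. No paired analysis was run, because the recovered libraries carry no number that ties them to the first samples or the repeats. A pairing read from the correlations below would be chosen from the data, so any such axis stays in the spread of the fits. No named gene or ratio of GA3 effects turned its direction. Whether more genes rose or fell depended on the setting in all comparisons but GA3 on PAC and PPZ. Among genes with a different GA3 effect, 314 were more positive and 341 more negative under trimmed mean scaling, and the negative side was larger in 6 of 8 refits without 1 library, from 10 against 43 to 137 against 154. For GA3 on PAC, 4028 were higher and 3892 lower with all groups in 1 fit, and 4584 and 4334 without the shallower PAC library. For bzr1-1D, limma-voom gave 4717 higher and 4524 lower, and more genes rose without either bzr1-1D library (5034 and 4632, 4305 and 4063). For PPZ, more genes rose under trimmed mean scaling (2373 and 2262), with no filter (2565 and 2416) and without either PAC and PPZ library (1288 and 1029, 1206 and 962). Log2 differences between the deeper and the shallower library correlated across genes between PAC and bzr1-1D (rho 0.431), GA3 on PAC and bzr1-1D (-0.381) and PAC and GA3 on PAC (-0.268), and less between PAC and PAC with PPZ (0.234) and the groups on PAC and PPZ (0.108), with the other 5 pairs of groups at -0.080 to 0.071. The sign depends on which library was deeper. Such a shared axis may mark the first samples and the repeats, which the labels name, or a batch that no label names.

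With an added 2-fold threshold, 1524 genes were called for GA3 on PAC, 596 for GA3 on PAC and PPZ and 2285 for bzr1-1D. The GA3 comparisons then shared 401 calls, and bzr1-1D shared 422 with GA3 on PAC and 205 with GA3 on PAC and PPZ. At an adjusted p under 0.01, GA3 on PAC and PPZ had 2151 calls, and the shared calls were 1751 for the GA3 pair and 1166 for bzr1-1D with GA3 on PAC and PPZ. Fewer genes pass a stricter threshold by construction. For GA3 on PAC and PPZ, limma-voom called 6970 genes, 6960 with no filter on low counts and 6851 with trimmed mean scaling, but 4543 with all groups in 1 fit. Its shared calls were 4202 for the GA3 pair and 3963 for bzr1-1D with GA3 on PAC and PPZ. The cause was not tested. Of the gene lists, camera with an estimated correlation called 0 of the 52, and 42 passed in the same direction with limma-voom calls, which leave out genes with unresolved reads. With the preset correlation 52 camera tests passed, not all of them for the same lists.

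Without each library in turn, limma-voom called 2613 to 8918 genes for GA3 on PAC (2613 without the deeper and 3718 without the shallower GA3 library), 4858 to 5740 for GA3 on PAC and PPZ, and 6769 to 9666 for bzr1-1D. The difference between GA3 effects held in 53 to 2742 genes, and PPZ changed 2168 to 7888. The lone library of a pair is assumed to vary like the other groups. Of the named results, 264 were called or not called alike by limma-voom and 5 gained a call. Without a library, up to 12 named calls ended, these without the deeper library with GA3 on PAC. The ratio of GA3 effects with over without PPZ stayed below 1 under every alternative run, at 0.477 to 0.622 for genes called without PPZ and 0.744 to 0.879 for genes called with it, and both extremes of each range came without the shallower and the deeper PAC library. Depth limits transcripts near 0 reads, such as PRE1 on PAC and PPZ, for which no fold is given. A pseudocount changes every fold to some degree. Pseudocounts of 1 and 10 moved 21 and 76 of the named folds beyond a tolerance not given here, and 259 and 204 counted as the same.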

Other observations

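The comparison of PPZ with no PPZ on PAC in wild type was added after the data were examined, and so were all tests in this part. PPZ lowered most measured SAUR, HLH and aquaporin genes and raised seed reserve and root markers. In all, 2261 genes were higher and 2337 lower among 19486 (limma-voom), of which 1115 and 489 changed at least 2-fold, and trimmed mean scaling gave 2373 and 2262. Of 19 SAUR genes 18 were lower (adjusted p = 5.7e-14 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with SAUR16 at -3.78 ± 0.33 (SE, 2 libraries per group). Of 16 HLH and bHLH growth regulators 14 were lower and 1 higher (adjusted p = 5.29e-10 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with PRE6 and PAR2 at -1.72 ± 0.15 and -1.82 ± 0.15 and PRE3, the exception, at 2.60 ± 0.38. Of 17 aquaporins 14 were lower (adjusted p = 2e-09 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), and of 25 Aux/IAA genes 13 were lower and 1 higher (adjusted p = 2.98e-05 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with IAA19 at -2.76 ± 0.25 and IAA6 going from 42.3 and 68.8 normalized reads to 0 in both libraries. Of 20 expansins 9 were lower and 6 higher (adjusted p = 0.00404 by Fisher's exact test, and camera adjusted p = 0.572 with an estimated correlation), and EXPA8 changed by -4.56 ± 0.22. The synthesis genes BR6OX2 and DWF4 were higher by 1.69 ± 0.14 and 0.72 ± 0.14, and the inactivation gene BAS1 changed by -1.69 ± 0.12. GA20OX1 and GA20OX2 changed by -2.07 ± 0.19 and -1.29 ± 0.17.

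All 13 seed reserve markers were higher with PPZ (adjusted p = 4.56e-11 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), for example CRU2 by 1.83 ± 0.12, and 9 of 10 root markers were higher (adjusted p = 9.16e-07 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), such as PRP3 by 2.37 ± 0.31. Of 13 jasmonate genes 6 were higher and 1 lower (adjusted p = 0.0174 by Fisher's exact test, and camera adjusted p = 0.656 with an estimated correlation), with VSP1 at 1.90 ± 0.24 and JAZ9 at -0.92 ± 0.14. Of 11 clock genes 6 were lower and 1 higher (adjusted p = 0.0109 by Fisher's exact test, and camera adjusted p = 0.54 with an estimated correlation), with PRR7 and GI at -0.93 ± 0.11 and -0.88 ± 0.10. The count of genes that PPZ changed was 7002 and 7888 without the deeper and the shallower PAC library, and 2317 and 2168 without those of PAC and PPZ.

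Across 19549 genes, the PPZ effect and the bzr1-1D effect had an r of -0.324 and -0.277, taken with a separate PAC and PPZ library for each effect in both ways, and genes are not independent replicates. For the PPZ effect and the GA3 effect on PAC, r was -0.085 and -0.156 with separate PAC libraries.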
